A study of Caenorhabditis elegans with 4 samples.

How the data were processed

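Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where CHD-3 sits on the genome of adult Caenorhabditis elegans. The labels list 4 libraries: 2 CHD-3 ChIP libraries and 2 input libraries, numbered 1 and 2 in each group. All came from fem-2(b245) hermaphrodites kept at 20 °C. Per the labels' protocols, frozen adult worms were ground, fixed with formaldehyde and sonicated. The ChIP used a rabbit polyclonal antibody, and libraries were amplified by PCR after size selection.

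Only peak lists were used, so no read counts, coverage or depth entered any comparison, and the depth of each library is unknown here. Per the submitters' processing notes, reads were aligned with BWA, with no version given, to ce10. Per the file headers, the coordinates are in the WormBase WS220 build. Each ChIP library has its own deposited peak list, and its source field names MACS. A separate list covers the whole series, and its source field names MACS v2. How the libraries were combined for that list, the thresholds, and the use of the input libraries are not given in the sources used here. Each deposited peak carries 1 score from the authors' peak caller, and no source names its scale. The scores start at 50.03 in replicate 1, 50.01 in replicate 2 and 1.3 in the series-level list, so the scores of the series-level list are not comparable with those of the replicates. In replicate 1, 539 nuclear peaks had a score of exactly 3100, and 16 did in replicate 2, so the highest peaks could not be ranked fully within a replicate. Scores were used to rank or filter peaks within 1 list and, for shared peaks, to correlate the replicates; where the scores of both replicates are given for a site, their sizes are not comparable, since they depend on the unknown depth.

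Only the 6 nuclear chromosomes entered the comparisons. The length of each was taken as the highest peak end over the 3 lists, which gave 100.3 Mb in all. Peaks overlapped when they shared at least 1 bp. Overlap was tested by a rotation permutation test, rotating 1 list along each chromosome by a random offset 9999 times, which keeps the number, widths and spacing of its peaks; the smallest one-sided p is 0.0001. The density ratio of X to autosomes was tested by 9999 rotations of the 6 chromosomes joined end to end, and the share of peaks in the arms by 9999 rotations within chromosomes. Both tests were two-sided, with 0.0002 as the smallest p. Arms were the outer 25% of a chromosome on each side. Peak spacing was set against 999 uniform placements of the same number of peaks, with 0.002 as the smallest two-sided p. Rank correlation of scores used 100000 permutations across peaks. Benjamini-Hochberg adjustment was made over the 3 lists, or over the 6 chromosomes within a list. Shares of peaks carry 95% exact Clopper-Pearson intervals, which treat peaks as independent and cover counting error only. Peaks and windows are not independent replicates, so these tests describe the lists, and the only replication is between the 2 ChIP libraries. The labels do not say whether these came from separate cultures.

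The rotation tests were checked on simulated lists about as long as the real replicate lists, with peaks placed uniformly and independently unless stated. With no effect, 4 of 100 simulations gave an overlap p under 0.05, 2 did for X and 4 for the arms. A list made with X at 1.5 times the autosomal density gave a ratio of 1.49, and one made with 40% of its peaks in the arms gave 40.8%. These values check how the ratio and the share were calculated, not the p-values.

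The regions named were fixed by a rule before the data were examined: the 10 highest-scoring series-level peaks that overlap a peak in both replicates. Regions chosen after their values were seen are marked as such. The alternatives set in advance were a 50% reciprocal overlap, midpoints within 250 bp, the upper 50% of each list by score, equal numbers of top-scoring peaks, covered length in place of peak number, the outer 33.3% on each side as arms, merging of peaks closer than 200 bp, and leaving out each replicate. The planned comparisons with promoters, gene features and gene lists, including tissue markers, were not made: the gene table used here is on WBcel235 and the peaks are on WS220, and positions were not carried from one build to the other. Peaks are therefore given by position. The input libraries, for which no peak list was used here, entered no comparison. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.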

Results

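CHD-3 is a chromatin-remodelling ATPase of the Mi-2 family, a component of NuRD-type complexes. Its occupancy was mapped by ChIP-seq in young adult hermaphrodites of the fem-2(b245) strain, in which a sex-determination gene needed for male development is mutated. The data comprised 2 ChIP libraries with an antibody against CHD-3, each with its own peak list, and another list called for the series as a whole. The 2 input libraries entered no comparison here. The comparisons ask how far the ChIP replicates found the same sites, which regions they shared, and how the sites were spread over the chromosomes. Coordinates are in WS220.

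CHD-3 peaks were found on all 6 nuclear chromosomes in both replicates, at 48.1 peaks per Mb in replicate 1 and 18.8 per Mb in replicate 2. Replicate 1 had 4822 nuclear peaks with a median width of 1699 bp, which covered 11.9 Mb or 11.9% of the nuclear genome. Replicate 2 had 1889 peaks with a median width of 1682 bp, which covered 3.99 Mb or 3.98%. The series-level list had 10512 nuclear peaks, but these were narrower, with a median of 335 bp, and covered 5.64 Mb or 5.63%. Wider peaks scored higher in each list, with a Spearman correlation across peaks of 0.83 in replicate 1, 0.74 in replicate 2 and 0.70 in the series-level list.

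Most peaks of replicate 2 overlapped a peak of replicate 1 by at least 1 bp. Of the 1889 peaks of replicate 2, 1677 did, or 88.8% (95% exact interval 87.3 to 90.2%). Rotated lists gave 20.5% on average and 41.0% at most, so the overlap was 4.34 times that of rotation (one-sided rotation permutation p = 0.0001, the smallest possible). In the other direction 1477 of the 4822 peaks of replicate 1 had a partner in replicate 2, or 30.6% (29.3 to 32.0%), against 8.17% under rotation (permutation p = 0.0001). The shares depended on the rule for a partner. For replicate 2 the share was 52.4% with a 50% reciprocal overlap and 39.7%, a minority, for midpoints within 250 bp. For replicate 1 it was 15.5% for midpoints within 250 bp and 62.0% with equal numbers of top-scoring peaks. Each of these stayed above rotation (permutation p = 0.0001). By length, the replicates shared 3.41 Mb, which was 28.7% of the length covered in replicate 1 and 85.5% of that in replicate 2.

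The sites that replicate 1 shared with replicate 2 were its strong and wide ones. In the lowest-scoring 10% of replicate 1, 4.14% of peaks (2.55 to 6.32%) had a partner, and in the highest 90.2% (87.2 to 92.7%) did. The lower bound of this highest 10% fell among peaks tied at 3100, and chromosome and position decided which of them it included. Shared peaks of replicate 1 had a median width of 2898 bp and a median score of 1849, against 1456 bp and 219 for the 3345 unshared peaks. Score and width had a Spearman correlation of 0.83 in replicate 1, and a wider peak meets the 1 bp rule more easily. These values therefore do not separate strength from width. Replicate 2 did not follow this order: 87.8% (82.3 to 92.1%) of its lowest-scoring and 77.7% (71.0 to 83.4%) of its highest-scoring peaks had a partner. Among 1290 pairs of peaks that overlapped one-to-one, scores rose together across peaks, with a Spearman correlation of 0.45 (two-sided permutation p = 1e-05, the smallest that the permutations can give) and Pearson's r of 0.36 on log10 scores. Since score rose with width in both replicates, these correlations do not separate agreement in score from agreement in width. With peaks at or above the score of 3100 removed from each list and pairs formed anew, the Spearman correlation was 0.23 over 898 pairs. Removing these peaks narrows the range of scores, which can by itself lower the correlation.

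**Figure D1:**
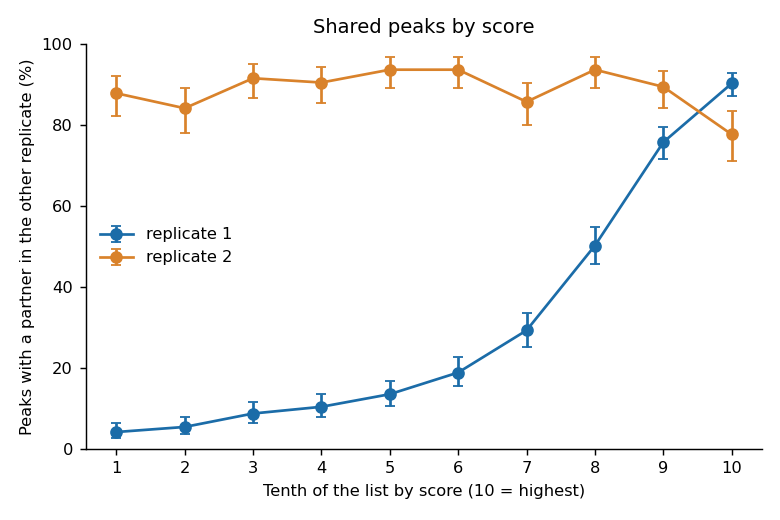
Share of peaks (%) with a partner in the other replicate, for each 10% of a replicate's list ordered by score from 1 (lowest) to 10 (highest), with 95% exact intervals as bars. In replicate 1 the share climbs from 4.14% to 90.2%, and in replicate 2 it stays between 77.7% and 93.7%. Higher-scoring peaks were also wider, which by itself gives more overlap. Replicate 1 peaks tied at a score of 3100 were divided between points 9 and 10 by chromosome and position.

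Both replicates had a peak at each of the 10 highest-scoring shared sites of the series-level list, as the rule for naming them required. The first lay on chromosome V at 15320518 to 15321703 with a series-level score of 114.32. It coincided with peaks of 3391 bp in replicate 1 and 3343 bp in replicate 2, both with a score of 3100. The second, on chromosome I at 13610093 to 13615917, was 5825 bp wide, scored 111.65, and also reached 3100 in both replicates. The site on chromosome II at 9631671 to 9633174 (104.68) reached 3100 in both replicates as well. A site on chromosome I at 14686331 to 14687630 (104.36) scored 3100 in replicate 1 and 2935 in replicate 2, and one near the left end of X at 142811 to 143719 (90.32) scored 3100 and 2945. Chromosome V held 3 further sites. The one at 9545956 to 9547869 (101.01) scored 3100 in replicate 1 and 346 in replicate 2. The pair at 6072130 to 6072983 (99.71) and 6088720 to 6089399 (97.17) scored 3100 in replicate 1, and 1796 and 1297 in replicate 2. The remaining 2 lay on chromosome IV. The site at 2619090 to 2619630 (95.62) scored 3100 in replicate 1 and 401 in replicate 2, and the site at 4725384 to 4725740 (91.08) scored 2811 and 82.7. The sizes of these scores are not comparable between replicates: over the 1290 one-to-one pairs the median score was 1635 in replicate 1 and 126 in replicate 2.

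Some peaks were many kilobases wide. Those given here were chosen for their width after the values were seen. No coverage was examined, so whether occupancy is continuous across them is unknown. The widest series-level peak was 11530 bp long, on X at 16929264 to 16940793. It lay within a peak of 18125 bp in replicate 1 and overlapped one of 12093 bp in replicate 2. A peak of 11154 bp on X at 6735136 to 6746289 lay within peaks of 17163 bp in replicate 1 and 15852 bp in replicate 2, the latter the widest of that list. On chromosome V at 10714977 to 10724202, a peak of 9226 bp lay within peaks of 23411 bp and 14674 bp. The third widest, on chromosome I at 15060225 to 15071353, was found in replicate 2 (11997 bp, score 3100) and had no peak in replicate 1; the right end of chromosome I carries the ribosomal DNA repeats. The widest peak of replicate 1, 31166 bp on chromosome II at 6819898 to 6851063, overlapped 1 peak of replicate 2 and 15 of the series-level list.

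**Figure D2:**
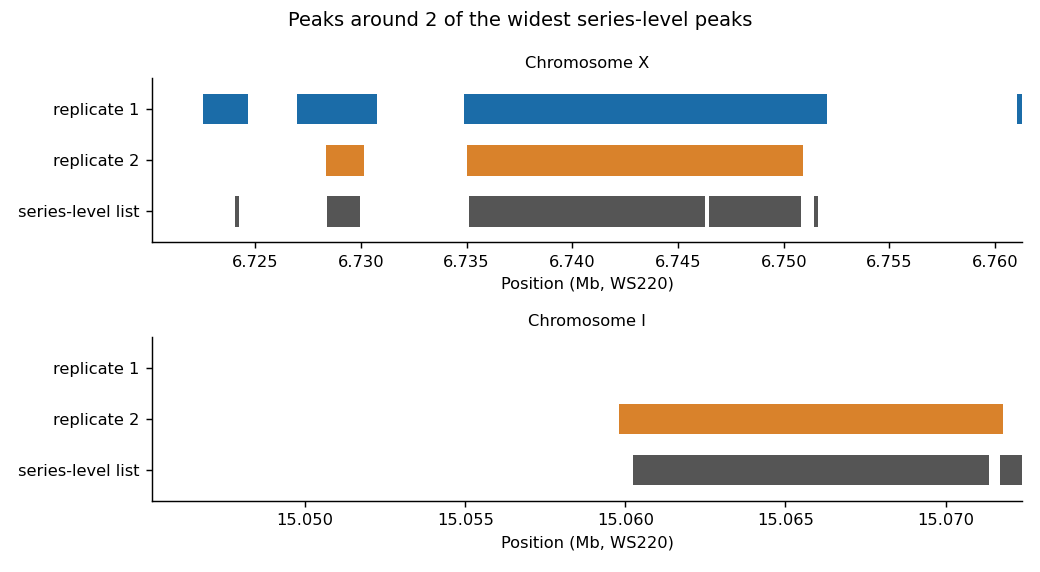
Peaks of the 3 lists (rows) along 2 regions around series-level peaks of 11154 bp (X, upper) and 11129 bp (chromosome I, lower), with position in Mb; each bar spans 1 peak to scale. The X region is covered in both replicates, and the region at the right end of chromosome I in replicate 2 but not in replicate 1.

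The series-level list overlapped nearly all peaks of replicate 2 and most of replicate 1 by at least 1 bp. It overlapped 1876 of the 1889 peaks of replicate 2, or 99.3% (98.8 to 99.6%), and 4273 of the 4822 of replicate 1, or 88.6% (87.7 to 89.5%). With a 50% reciprocal overlap these shares were 64.3% of replicate 2 and 8.79% of replicate 1. Of its own 10512 peaks, 2728 (25.95%) overlapped both replicates, 5561 (52.9%) replicate 1 alone, 331 (3.15%) replicate 2 alone and 1892 (18.0%) neither. These classes depended on the overlap rule: with a 50% reciprocal overlap 3.11% matched both, 0.923% replicate 1 alone, 8.45% replicate 2 alone and 87.5% neither. Replicate 2 alone was then the larger of the classes with 1 replicate. A series-level peak of the median 335 bp cannot cover 50% of a replicate peak of median width, 1699 or 1682 bp. Peak width thus limits matches by this rule, and they do not by themselves show which replicate holds a site. By the 1 bp rule, the peaks found in both had a median series-level score of 14.46 and a median width of 743 bp, against 4.56 and 214 bp for those found in neither. The 331 peaks that matched replicate 2 alone had a median score of 10.42, against 5.92 for those that matched replicate 1 alone. These are descriptions, since the lists may rest on the same reads. A peak of replicate 1 overlapped 1.72 series-level peaks on average and a peak of replicate 2 overlapped 1.63. A minority of peaks overlapped 2 or more series-level peaks, 38.1% in replicate 1 and 43.6% in replicate 2.

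Peak density on X, a chromosome largely silent in the germline, was not distinguishable from that on the autosomes. Replicate 1 had 55.2 peaks per Mb on X and 46.6 on the autosomes, a ratio of 1.19, and replicate 2 had 20.3 and 18.5, a ratio of 1.10. The mean ratio was 1.14 ± 0.063 (SD, n = 2). Rotation of the joined chromosomes gave ratios from 0.77 to 1.24 for this mean in 95% of draws (two-sided rotation permutation p = 0.313). The ratio in the series-level list was 1.15. Adjusted over the 3 lists, p was 0.418 for replicate 1, 0.643 for replicate 2 and 0.535 for the series-level list. Among the chromosomes, III was the densest in each list, with 56.8, 21.7 and 125.3 peaks per Mb in replicate 1, replicate 2 and the series-level list, and V the sparsest, with 39.0, 15.6 and 86.4. Neither passed the test, with adjusted p of 0.282 for both in replicate 1, 0.67 for both in replicate 2, and 0.426 and 0.556 in the series-level list.

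CHD-3 peaks were fewer in the chromosome arms, the repeat-rich and highly recombining outer parts of the autosomes in this species, than in the centres. Arms were taken as 50% of the length of each of the 6 chromosomes, X included, with no account of how well reads map there. The arms held 40.1% of the peaks of replicate 1 (1936 of 4822), 46.9% of replicate 2 (886 of 1889) and 42.5% of the series-level list (4465 of 10512). The mean of the replicates was 43.5 ± 4.78% (SD, n = 2). The two-sided rotation permutation p, adjusted over the 3 lists, was 0.0003, 0.0126 and 0.0003. In replicate 1 the centre was denser than either arm on each of the 6 chromosomes, and the arm share ranged from 35.3% on V to 47.3% on X. The centre of V had 50.5 peaks per Mb against 31.4 and 23.7 in its left and right arms, and the centre of X had 58.1 against 46.7 and 57.8. In replicate 2 the arm share ranged from 43.4% on IV to 50.3% on II, and was 50% on X. There the right arm was the densest part of II (24.1 peaks per Mb, against 18.8 in the centre) and of X (21.7 against 20.3), and on V it had 17.4 against 17.3. The arm share of replicate 2 no longer passed the test in the upper 50% of its list by score (47.7%, rotation permutation p = 0.182) or with the outer 33.3% on each side as arms (65.96% of peaks in 66.7% of the length, p = 0.629).

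**Figure D3:**
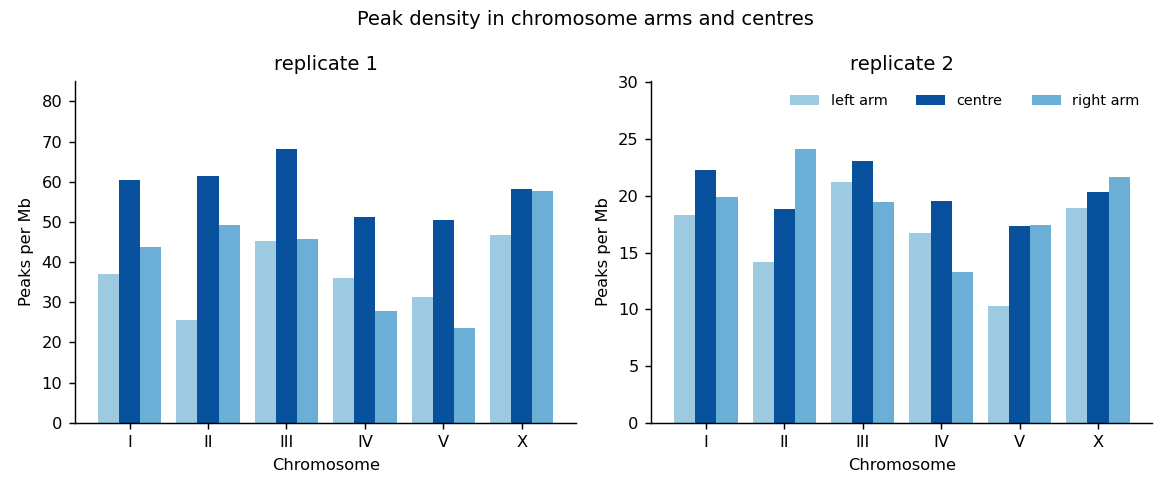
Peaks per Mb (y axis, separate scale per panel, from 0) in the left arm, centre and right arm of each chromosome (x axis) for replicate 1 (left) and replicate 2 (right); each bar is 1 value of 1 library, with no error. The centre is the highest bar on each chromosome in replicate 1, and the right arm is the highest on II, V and X in replicate 2.

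Single windows of 1 Mb showed where the sites gathered. Over the 97 full windows, replicate 1 had between 14 and 94 peaks with a median of 48, and replicate 2 between 5 and 31 with a median of 19. The densest window of replicate 1 was on chromosome I from 9000001 to 10000000, with 94 peaks in replicate 1, 26 in replicate 2 and 187 in the series-level list, the most in that list too. Replicate 2 reached 31 peaks in windows on III from 3000001 to 4000000 and on X from 4000001 to 5000000, where replicate 1 had 78 and 74. The window with the fewest peaks in replicate 1 was on V from 17000001 to 18000000, with 14 peaks, and replicate 2 had 8 there. Across windows the counts of the replicates had a Spearman correlation of 0.55, which is a description, since neighbouring windows are not independent.

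**Figure D4:**
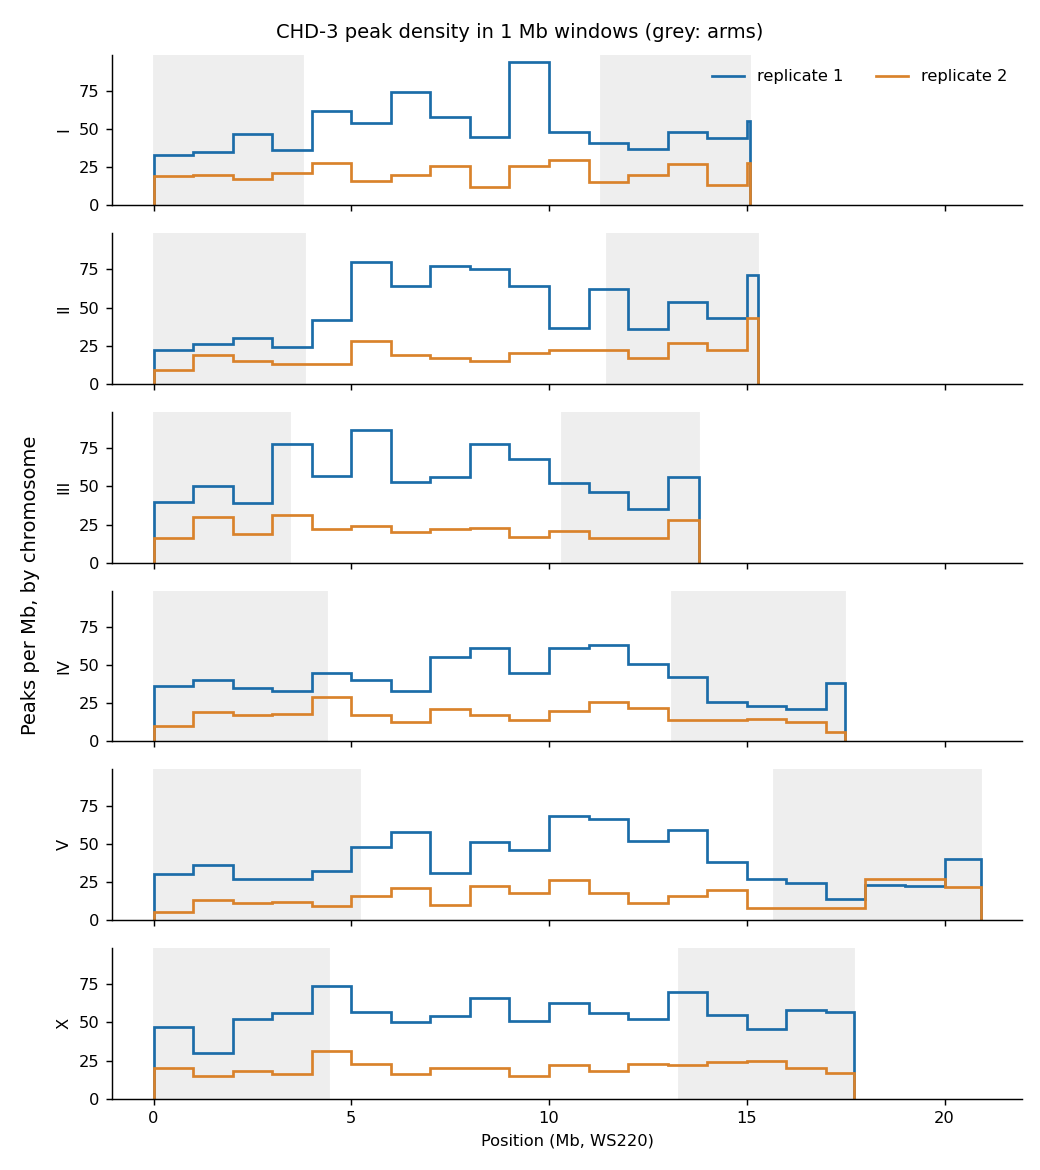
Peaks per Mb (y axis) in 1 Mb windows along each chromosome (x axis, Mb) in replicate 1 and replicate 2; the last window of a chromosome is shorter and is scaled to its length, and grey marks the arms. Replicate 1 peaks in the centre of I with 94 peaks in 1 window, and on the right arm of V replicate 2 has 27 peaks in each of 2 windows where replicate 1 has 23 and 22.

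Sites lay closer together than uniform placement would put them. The median distance between neighbouring peak midpoints was 10.8 kb in replicate 1, where uniform placement gave 14.2 kb (95% of draws 13.8 to 14.6 kb). In replicate 2 it was 29.9 kb against 36.4 kb (34.7 to 38.2 kb), and in the series-level list 2.45 kb against 6.54 kb (6.41 to 6.66 kb). Each had a two-sided p of 0.002, the smallest the draws can give, which adjustment over the 3 lists left at 0.002. Uniform placement ignores the differences in density between arms and centres, which can by themselves shorten the median distance. The test therefore does not show clustering on a local scale. Merging peaks closer than 200 bp moved the ratio to uniform placement in the series-level list from 0.38 to 0.55. In replicate 1 the ratio moved from 0.76 to 0.80, and in replicate 2 from 0.82 to 0.86.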

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

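Peaks on the mitochondrial genome are a signal outside the comparisons, which used nuclear chromosomes. The series-level list held 8 of them, which covered 89.3% of the sequence up to its highest mitochondrial peak end, with a top score of 12.86. Replicate 1 held 1 mitochondrial peak that covered 99.7% of that length with a score of 3230, and replicate 2 held none. By printed value that score was the 4th highest of its list. Its place relative to the 539 nuclear peaks at exactly 3100 is unknown, since no source explains that repeated value. The input libraries were not compared, so no background level was set beside these values, and no explanation was tested.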

How the results depend on the processing

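Of 50 alternatives to 20 values, 38 kept their direction and their side of the threshold or stayed within their interval, 2 lost significance, 10 moved and 0 reversed. Of the alternatives, 3 were added after the data were seen. This tally does not measure robustness. Tested values counted as kept whatever their size, as when the overlap share of replicate 2 fell from 88.8% to 39.7%. X ratios counted as kept when they again did not pass the test. Untested shares were judged by their interval. For X and the arms, leaving out a replicate or taking the series-level list repeated values counted elsewhere. The overlap of the replicates remained above rotation under each alternative run, with 39.7 to 81.9% of replicate 2 peaks and 15.5 to 62.0% of replicate 1 peaks shared. The rank correlation of scores ranged from 0.23 to 0.55, the lowest without peaks at or above 3100, an added alternative. With a 50% reciprocal overlap, the share of series-level peaks in both replicates was 3.11%, in replicate 1 alone 0.923%, in replicate 2 alone 8.45% and in neither 87.5%. The list then held 8.79% of replicate 1 and 64.3% of replicate 2 peaks. The series-level median width was 335 bp, and the 10th percentile of width was 1073 bp in replicate 1 and 1134 bp in replicate 2. A median series-level peak thus cannot cover 50% of most replicate peaks, so width by itself kept these shares low. Why replicate 2 matched more than replicate 1 was not tested. In the upper 50% of each list by score, the shares in both, replicate 1 alone, replicate 2 alone and neither were 21.2%, 46.5%, 4.64% and 27.6%; fewer peaks were available to match. The arm share of replicate 2 lost significance in its upper 50% by score (47.7%) and with the outer 33.3% on each side as arms (65.96%); the cause was not tested. With 2 replicates, leaving out 1 returns the value of the other, so this repeats results given above and is no separate check. The arm shares were 40.1 to 46.9%, both past the threshold, and the X ratios 1.10 to 1.19, neither past it. Overlap and the score correlation need both replicates, so neither could be left out there. The promoter, feature class and gene list alternatives were not run. No paired analysis was possible because no peak list of the input libraries was used here. The unknown depth of the libraries limits any reading of the smaller number of peaks in replicate 2.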

Other observations

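The 2 tests of chromosome arms, with equal list lengths and without the unshared peaks of replicate 2, were set before their results were known but after the arm shares of the full lists had been seen. The test of arms among peaks without a partner was also set before its result was known. The other tests and counts given here were chosen after the values were seen. Peaks lay on the first bases of the nuclear chromosomes more often than placement by rotation gives. The series-level list had a peak on the first 2 bp at the left end of 6 of 6 chromosomes, with scores from 5.17 on IV to 35.09 on II. Rotation put a peak over these bases on 0.34 chromosomes on average and 4 at most (one-sided rotation permutation p = 0.0001), which argues against random placement of the peaks. Replicate 2 had such peaks on 5 chromosomes (I, II, III, V and X; permutation p = 0.0001) and replicate 1 on 2 (III and X; permutation p = 0.156). Telomere repeats are a candidate explanation that needs the sequence and was not tested. Right ends were not tested, since chromosome lengths were taken from the peaks themselves.

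The arms held 40.1% of the peaks of replicate 1 and 46.9% of those of replicate 2, a difference of 6.75 percentage points. One candidate explanation, that the longer list of replicate 1 adds weak peaks in the centres, was argued against: held to its 1889 top-scoring peaks, replicate 1 had 36.7% in the arms, and the difference was 10.2 points (one-sided joint rotation permutation p = 0.0004). Whether peaks found in replicate 2 alone are the whole cause stays open. Without them 44.2% of the peaks of replicate 2 lay in the arms, still 4.10 points more than in replicate 1 (one-sided joint rotation permutation p = 0.0041). By the rule set beforehand, a p under 0.05 counted against this explanation. But the test set this share against all peaks of replicate 1. Its own unshared peaks were kept and lay in the arms in 37.9% of cases, so the test does not decide, although it was set to do so. Shared peaks overlap by definition, so the similar shares of the shared peaks (45.2% in replicate 1 and 44.2% in replicate 2) decide nothing either. Differences in library depth or in the authors' use of the input remain open, and no biological explanation was tested, since both libraries have the same labels.

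The 212 peaks of replicate 2 without a partner in replicate 1 were spread over its range of scores: 52 of them (24.5%) were in the lowest-scoring 20% of the list and 42 (19.8%) in the highest-scoring 10%, against 146 of the 1677 peaks with a partner (8.71%). Their median score was 159.88, against 129.15 for the peaks with a partner. These values argue against weak peaks near the calling threshold as the whole cause. They lay in the arms in 67.9% of cases, against 44.2% of partnered peaks. Whether they come from sequence concentrated in the arms stays open, because the lower peak density of replicate 1 in the arms could also leave peaks of replicate 2 there without a partner, which was not tested. Chromosome V held 66 of the 212, and 326 of all 1889 peaks of replicate 2; in its last 10%, 22 peaks had no partner and 35 had one.

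The series-level peaks that overlapped neither replicate had a median score of 4.56, against 14.46 for those that overlapped both. Weak signal near the threshold of that list remains possible, but higher-scoring peaks were also wider, which by itself gives more overlap, so these values do not decide it. The same score of 33.55 was given to 12 series-level peaks that ranged from 470 to 11129 bp in width. Of these, 8 were among the 331 that matched replicate 2 alone, and 4 matched both replicates. The next most frequent score of 30 or more, 30.92, was given to 8 peaks.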
